A study of Homo sapiens with 6 samples.

How the data were processed

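Chromatin accessibility was measured by ATAC-seq in MCF-10A cells carrying wild-type PIK3CA, PIK3CA E545K or PIK3CA H1047R, with 2 samples per genotype. Per the labels, parental cells were maintained with 20 ng/ml EGF and the knock-in lines without EGF, and all cells spent the last 24 h in assay medium with 1% stripped serum and 0.2 ng/ml EGF. The authors trimmed reads with Trim Galore 0.4.0, aligned them to hg38, processed alignments with SAMtools and called peaks with Genrich 0.6.1 on both samples of a genotype together, so that 1 peak list stands for each genotype. The aligner is not given in the sources used here.

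In the deposited lists the signal value of a peak is the area under the peak caller's curve over the peak, from both samples of a genotype together. The deposited -log10 p is that of the summit position, as the authors' peak caller wrote it, and the column for adjusted values held no values and was not used. These are the authors' values for each peak and served only to describe, rank or filter peaks within a list. The smallest area was 200 in each list, the smallest gap between peaks was 101 bp, and each list covered the 22 autosomes only. Sequencing depth and values per sample are not given by these lists, so depth is unknown and no test across samples was made. All peaks lay within the hg38 chromosome lengths of the reference. Gene models were those of GENCODE release 44.

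Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A peak had a partner when it overlapped a peak of the other list by at least 1 bp. Strong peaks were the upper 50% of a list by area. Shares carry a Wilson 95% interval for counting error. Peaks were classed by midpoint as promoter (within 1 kb of the start of the canonical transcript of a protein-coding gene), exon, intron or intergenic, and a promoter had a peak when any peak overlapped that window. Peaks of the 3 lists that touched were merged into 120615 regions. Each peak went to the protein-coding gene with the nearest start within 100 kb, and the net of a gene was its strong unpartnered peaks in 1 list minus those in the other.

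The 21 gene lists covered the PI3K-AKT-mTOR pathway, FOXO targets, EGF-MAPK early response, ERBB receptors and ligands, basal and luminal markers, epithelial-mesenchymal transition, cell junctions, glycolysis and hypoxia, sterol and fatty acid synthesis, amino acid response, inflammation, interferon response, TGF-beta and WNT signalling, YAP and TEAD targets, p53 targets, HOX genes, keratinocyte differentiation, immune markers, neural and endothelial markers and housekeeping genes. The net per gene of each list was placed among 10000 random lists of the same size matched on regions per gene in 5 bins. Of 63 such percentiles, 7 lay outside 2.5 to 97.5, where chance gives 3.15. The 25 motifs were sought within 100 bp of the summit, and shares in strong unpartnered peaks were set against 1000 draws of shared peaks of the same list matched on GC content and area decile. Of 150 motif and set pairs, 51 lay outside the central 95% of the draws, where chance gives 7.5. Shared regions holding a single peak of each list, 69662 in all, were ranked by area within each list, and the shift of the percentile rank was summarised in windows of 5 Mb with at least 20 such regions. The interval of the shift on the short arm of chromosome 5 came from 1000 bootstrap resamples.

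Named genes followed a rule: per comparison and direction the 5 genes with the highest net of at least 3, the 5 genes with the largest promoter peak present in 1 list only, up to 4 members per gene list with the largest net and up to 4 with a promoter peak in some lists only, and PIK3CA. The comparisons, gene lists, motifs, naming rule and most alternatives were set before the data were examined. Alternatives were a stricter peak threshold, lists reduced to their 89416 strongest peaks, wider and narrower definitions of overlap, distance and promoter, all unpartnered peaks, and whole peaks for motifs. Strength by summit value for gene lists, motifs and loci, further settings for loci, and leaving out the short arm of chromosome 5 and the end of chromosome 8 were chosen after seeing the data.

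The counting was checked against bedtools 2.31.1, with 0 differences over 12 counts. Tested on simulated data, 2000 of 2000 removed peaks were found and 0 of 96910 kept peaks were called. Random gene lists lay outside the central 95% in 1 of 60 cases and lists with added peaks in 20 of 20. Unchanged motifs lay outside in 4 of 40 cases, and a motif planted at 2 times its share gave a ratio of 1.95. RNA, which the labels mention, was not analysed here. Some genes that the naming rule takes are not reported here.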

Results

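Accessible chromatin was profiled by ATAC-seq, in which the transposase Tn5 cuts open DNA, in MCF-10A cells, a non-tumorigenic human breast epithelial line. Parental cells with wild-type PIK3CA (WT) were set beside knock-in lines carrying PIK3CA E545K, in the helical domain of the catalytic PI3K subunit, or H1047R, in its kinase domain. Each genotype was represented by 2 samples, 6 in all, and by 1 pooled peak list. The lists therefore carry no replicate values, sequencing depth is unknown, and all differences below describe 3 lists without a replicate check. Genotype also went with maintenance medium, since parental cells were kept in 20 ng/ml EGF and both knock-ins without EGF until all were moved for 24 h to medium with 0.2 ng/ml EGF.

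PIK3CA itself (ENSG00000121879.6, hg38 chromosome 3, 179148114 to 179240093, plus strand) had a promoter peak in each list, with an area of 7476 in WT, 6416 in E545K and 7244 in H1047R. No strong peak near PIK3CA lacked a partner in another list, a partner being a peak of that list overlapping by at least 1 bp. Strong peaks were the upper 50% of a list by area. The area is that under the peak caller's curve over the peak, so it depends on width as well as height and is not a read count. Peak positions do not show the edited bases, so the genotypes rest on the labels.

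The WT list held 98910 peaks covering 67.4 Mb, the E545K list 89416 peaks covering 69.7 Mb and the H1047R list 106747 peaks covering 72.4 Mb. Peaks were wider in E545K, with a median of 539 bp against 466 bp in both other lists, and lower, with a median summit -log10 p of 3.97 against 4.25 in WT and 4.14 in H1047R. In all, 5.41% of E545K peaks exceeded 2000 bp against 3.90% in WT and 3.91% in H1047R. The strongest peak of each list covered the same region nearest TNS4, a focal adhesion gene (chromosome 17, 40467959 to 40502307 in WT, area 117900). The next strongest in WT were an intronic peak nearest ADAMTSL4 (chromosome 1, 150548309 to 150576578, area 76970) and an intergenic one near KRT17, a basal keratin gene (chromosome 17, 41612000 to 41626679, area 72760). In E545K they were the ADAMTSL4 peak (area 82110) and a peak in an intron of PLEC, which encodes the cytoskeletal linker plectin (chromosome 8, 143910461 to 143947437, area 61560). In H1047R they were an exonic peak near C1orf74 (chromosome 1, 209765361 to 209808866, area 95440) and one nearest CAMK1G (chromosome 1, 209600022 to 209632260, area 69590). By midpoint, 11.6% of WT peaks (95% Wilson interval, which here and below covers counting error only, 11.4 to 11.8), 12.7% of E545K peaks (12.5 to 12.9) and 10.9% of H1047R peaks (10.7 to 11.1) lay within 1 kb of the start of a protein-coding gene, while introns held 42.5%, 41.7% and 43.3%.

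Promoters differed little between the genotypes. Of 19103 autosomal protein-coding genes, 12509 had a promoter peak in all 3 lists and 5725 in none, which left 869 with a peak in some lists. Basal and luminal identity genes were largely open throughout: 19 of 23 basal and myoepithelial markers, 17 of 23 luminal markers, all 28 EGF-MAPK early response genes, all 23 p53 targets and all 26 housekeeping genes with a gene model had a promoter peak in each list. The HOX genes were split, with a promoter peak in each list for 14 of 39 members and in no list for 20. Markers of other cell types mostly lacked a promoter peak, with none in any list for 21 of 26 immune markers and 16 of 22 neural and endothelial markers.

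The E545K and WT comparison asked which regions gained or lost a called peak in cells with the helical-domain mutation. Here and below, a peak is given to the gene with the nearest start within 100 kb. Peaks said to be near or at a gene can thus lie outside it. By area, 6 strong E545K peaks near ALDH1A3, which oxidises retinal (ENSG00000184254.17, chromosome 15, 100877714 to 100916626), and 5 near DHRS3, a retinal reductase (chromosome 1, 12567910 to 12618210), had no partner in WT, and none pointed the other way, but with strength by summit value both genes had a net of 0. Peaks covered 56.3% of the ALDH1A3 gene body in E545K, 26.9% in H1047R and 3.38% in WT. The E545K peaks there were wide and low, with a median of 1305 bp and a summit -log10 p of 2.79. The other leading loci lay together near the end of chromosome 8, where ADGRB1, an adhesion receptor gene, had 9 such peaks, ARC, known as a neuronal activity gene, 8, and ZC3H3, a zinc-finger gene, 6. The ARC gene body itself carried 1 peak in each list, so the 8 were not within the gene. WT in turn held 6 strong peaks at AJAP1, a gene of adherens junctions (chromosome 1, 4654609 to 4792534), 3 at SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling (chromosome 5, 142310427 to 142326455), and 3 at TSHZ3, a zinc-finger transcription factor gene (chromosome 19, 31149979 to 31349436), that E545K lacked.

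By area, E545K held unpartnered peaks at kallikrein genes of the keratinocyte differentiation list. KLK5, KLK6, KLK7 and KLK10, neighbouring serine protease genes expressed in stratified epithelia, each had 1 strong E545K peak with no WT partner, and no list member had the opposite, a net of 0.17 peaks per gene that lay at the 97.9 percentile of 10000 random gene lists matched on regions per gene, and at 57.0 with strength by summit value. These kallikrein genes lie close together on chromosome 19 (50943303 to 51020175), and the random lists were not matched on such proximity. The percentile thus treats 1 stretch of the genome as separate genes. The promoters of KLK10 (area 2060 in E545K and 663 in H1047R) and KLK7 (820 and 643) had a peak in both knock-ins and none in WT. The PI3K-AKT-mTOR list moved the other way, with no strong E545K peak and 5 strong WT peaks lacking a partner, among them 1 each at GAB2, IRS2 and RICTOR (net -0.15 per gene, 0.85 percentile, and 14.4 with all unpartnered peaks). The TGF-beta and WNT list had 1 such peak in E545K and 7 in WT, led by TGFBR1 with 2 and DKK1, SMAD3 and SMAD7 with 1 each (net -0.19, 0.57 percentile, and 9.82 by summit value and 69.6 with all unpartnered peaks). The FOXO target list had 3 peaks on either side, with FBXO32 on the E545K side and IRS2, KLF6 and RICTOR on the WT side. EGF-MAPK early response genes had 3 in E545K and 5 in WT, of which SPRY4 gave 3. The ERBB list had 2 on either side, and EREG, which encodes the EGF receptor ligand epiregulin, had a promoter peak only in WT (area 1014).

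Of the E545K peaks, 11252 had no WT partner (12.6%, interval 12.4 to 12.8), and of the WT peaks 20076 had no E545K partner (20.3%, 20.0 to 20.6). Among strong peaks, 1139 of E545K (2.55%, 2.41 to 2.70) and 1052 of WT (2.13%, 2.0 to 2.26) lacked a partner. With lists of equal length the counts were 14106 and 13697, and 1364 and 687 among strong peaks. The strongest were, in E545K, an exonic peak 16302 bp from the start of IFITM10 (chromosome 11, 1731438 to 1737147, area 7440), an exonic one near EMP1 (chromosome 12, 13211228 to 13216710, area 6059) and one in DHRS3 (chromosome 1, 12582611 to 12586552, area 4691). In WT they lay far from ENSG00000288712 (chromosome 6, 69179649 to 69181124, area 4478), in an intron near CDYL (chromosome 6, 4835371 to 4836293, area 3414) and between genes near HOPX (chromosome 4, 56613011 to 56614017, area 3205). Promoters were rare among them, with 3.51% (2.59 to 4.75) of these E545K peaks against 23.4% (23 to 23.8) of strong E545K peaks with a partner.

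A peak marked 329 promoters in E545K and not in WT, and 270 in WT and not in E545K. The largest were peaks that reached the promoter window in 1 list and overlapped a peak of the other list that did not: LIME1 (area 8209), PLEKHG6 (7875), RHBDL1 (6939), SLC39A4 (5990) and RRAD (4838) in E545K, and NAGS (5738), SLC17A7 (5330), KIR2DL1 (3577), ZNF385A (3292) and GNG3 (2718) in WT. In 287 and 244 of these promoters the peak had no partner at all. Among those, chosen after the values were seen, E545K had PLCH2 (area 2293), a phospholipase C gene, ZNF93 (2234) and KLK10, and WT had BRSK2 (2407), MTARC2 (2085) and WT1, a zinc-finger transcription factor gene (2023), which had no promoter peak in H1047R either.

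With strength by area and the search near the summit, the AP-1 motif was rarer than in matched shared peaks in the strong unpartnered peaks of each ordered pair. This did not hold in other settings for H1047R peaks absent from E545K, where the ratio was 1.17 by summit value and 1.4 with all unpartnered peaks. It lay within 100 bp of the summit of 8.87% (interval 7.35 to 10.7) of the E545K peaks absent from WT against 29.4%, a ratio of 0.301. In the WT peaks absent from E545K the share was 25.5% (22.9 to 28.2) against 33.6%, a ratio of 0.758. In the E545K peaks NRF2 and KLF-SP motifs stood at 0.697 and 0.721 times the matched share, which turned to 1.22 and 1.29 over whole peaks. The RUNX motif lay within 100 bp of the summit of 5.80% of these E545K peaks (4.58 to 7.31) against 4.29%, a ratio of 1.35, and the GATA motif in 2.90% (2.07 to 4.04) against 1.94%, a ratio of 1.49. In the WT peaks absent from E545K, a FOXO element was found in 3.14% (2.24 to 4.37) against 1.58%, the STAT motif in 5.13% (3.96 to 6.64) against 3.19%, the NF-κB motif in 2.95% (2.08 to 4.15) against 1.75% and the glucocorticoid receptor element in 1.14% (0.65 to 1.98) against 0.55%, while RUNX stood at 0.74 times and SOX at 0.85 times the matched share. The general forkhead motif, sought in the same WT peaks, stood at 1.13 times the matched share, inside the draws. When all unpartnered peaks were used the glucocorticoid receptor ratio went from 2.08 to 0.94 and the NF-κB ratio from 1.69 to 1.06, inside the draws. Over whole peaks the E545K peaks also held more FOXO (1.54), STAT (1.35), NF-κB (1.48) and glucocorticoid receptor elements (1.84) than matched peaks. Draws were not matched on peak width, so whole-peak ratios here and below also depend on the length searched. The draws for near-summit shares were matched on area but not on summit height or width. Those ratios can therefore also depend on peak shape. Ranked by summit value, 658 E545K peaks were strong and unpartnered, and ADGRB1, ARC and ZC3H3 had a net of 0, whereas AJAP1 kept 6.

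The H1047R and WT comparison asked the same of the kinase-domain mutation. H1047R held strong peaks without a WT partner at SORCS2, a sortilin-family receptor gene (5, chromosome 4, 7192538 to 7742836), ITGB6, which encodes an epithelial integrin that activates TGF-beta (5, chromosome 2, 160099667 to 160200313), TRAF3IP3 (4, chromosome 1, 209756032 to 209782320), CRISPLD2 (4, chromosome 16, 84819985 to 84920768) and TTC39C (4, chromosome 18, 23992773 to 24135610). WT held 6 at AJAP1 and 3 at TSHZ3, the loci also lacking in E545K, and in addition 4 at NEDD9, a focal adhesion scaffold gene (chromosome 6, 11183298 to 11382348), and 4 at YWHAZ, an adapter protein gene (chromosome 8, 100916523 to 100953388). Peaks covered 55.4% of the YWHAZ gene body in WT, 61.8% in E545K and 12.6% in H1047R.

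Among 22 measured p53 targets, 8 strong H1047R peaks at 5 genes had no WT partner and no strong WT peak lacked an H1047R partner, with 2 each at MDM2, BTG2 and TP53INP1 and 1 at SPATA18 (net 0.36 per gene, 99.8 percentile), while 17 members had a net of 0. The list no longer stood out with lists of equal length (77.8 percentile) or strength by summit value (77.4). The MDM2 gene body carried 3 peaks in both WT and H1047R, covering 4.88% and 4.87%, and 8 in E545K, covering 16.9%. Genes of epithelial-mesenchymal transition and fibroblasts had 0 in H1047R and 3 in WT, 2 at TGFBI, a TGF-beta-induced matrix gene, and 1 at VIM, which encodes vimentin (net -0.12, 1.31 percentile, and 6.20 with lists of equal length and 19.7 by summit value, and with all unpartnered peaks the net turned to 0.12). The housekeeping list, set as a control, stood at the 0.735 percentile, with 4 WT peaks at YWHAZ and 1 H1047R peak at TFRC. By summit value it stood at 66.3, with the net turned to 0.0417. Cell junction genes had 6 peaks in H1047R, among them CLDN1, DSG2, DSP and GRHL1, and 1 in WT (net 0.22, 90.7 percentile). EGF-MAPK early response genes had 9 in H1047R, with ERRFI1, a feedback inhibitor of the EGF receptor, giving 2, and 5 in WT (61.2 percentile). The NF-κB and inflammatory list had 5 in H1047R, 2 of them at TNFAIP3, and 2 in WT (65.8 percentile). The PI3K-AKT-mTOR list had 1 on either side, PIK3CG in H1047R and PIK3IP1 in WT.

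Of the H1047R peaks, 19139 had no WT partner (17.9%, 17.7 to 18.2), and of the WT peaks 10929 had no H1047R partner (11.0%, 10.9 to 11.2). Among strong peaks the counts were 1574 (2.95%, 2.81 to 3.10) and 690 (1.4%, 1.3 to 1.5). With lists of equal length 13117 and 12671 peaks lacked a partner, and 2.34% and 1.57% of the strong peaks. The strongest were, in H1047R, the 10107 bp peak at the TRAF3IP3 promoter (chromosome 1, 209754180 to 209764286, area 13320), an intronic peak nearest CTNNB1, the gene of beta-catenin (chromosome 3, 41242795 to 41249883, area 7846), and one in PTPRN2 (chromosome 7, 158451939 to 158455318, area 5830). In WT they were an intronic peak at ITGB4, the hemidesmosome integrin gene (chromosome 17, 75735638 to 75746913, area 11120), one at FASN, the fatty acid synthase gene (chromosome 17, 82078513 to 82092154, area 8668), and one in DST, the gene of dystonin (chromosome 6, 56624109 to 56628980, area 7012).

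A promoter peak was present in H1047R and absent in WT for 341 genes and the reverse for 196. Apart from TRAF3IP3 (area 13320), whose peak had no partner, the largest reached a neighbouring peak of the other list: C11orf96 (4076), ENSG00000285920 (3352), GAMT (2479) and RHBDL1 (2423) in H1047R, and MAMDC4 (11860), ENSG00000257341 (11440), ANXA2R (6399), NAGS (5738) and GNAT1 (5265) in WT. CSF3, the gene of the granulocyte growth factor G-CSF, had a promoter peak in WT alone (area 2414), and CXCL10, an interferon-induced chemokine gene, in H1047R alone (429). CCND2, a D-type cyclin gene chosen after its value was seen, had an unpartnered promoter peak in WT (1797) and E545K (1651) and none in H1047R.

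The NF-κB motif was the leading sequence of H1047R peaks, in 5.08% (interval 4.10 to 6.28) of the 1574 strong peaks without a WT partner against 2.43% of matched shared peaks, a ratio of 2.09. The HOX-PBX motif stood at 2.22% (1.60 to 3.08) against 1.27%, a ratio of 1.75. AP-1 stood at 0.644 times the matched share in H1047R and 0.591 times in the WT peaks without an H1047R partner, and at 1.21 and 0.604 times with all unpartnered peaks. In H1047R SOX was at 1.19 times and STAT and TEAD at 0.71 and 0.78 times the matched share, which turned to 1.09 and 1.13 when whole peaks were searched. The 690 WT peaks without an H1047R partner carried more TEAD motifs (13.2%, 10.9 to 15.9, against 9.50%), STAT motifs (5.36%, 3.92 to 7.30, against 3.24%), FOXO elements (2.75%, 1.77 to 4.26, against 1.56%) and glucocorticoid receptor elements (1.45%, 0.79 to 2.65, against 0.57%). In these WT peaks the NF-κB motif was also in excess (3.33%, 2.23 to 4.95, against 1.86%, a ratio of 1.79). The general forkhead motif there stood at 0.872 times the matched share, inside the draws. With lists of equal length and with strength by summit value TRAF3IP3 had a net of 1 under either; by summit value ITGB6 had 1 and TTC39C, NEDD9 and YWHAZ had 0. With all unpartnered peaks the NF-κB ratio stayed at 2.26 in H1047R, while in WT it went from 1.79 to 0.57. In other settings both sides kept the excess, with 2.6 in H1047R and 2.25 in WT by summit value. Over whole peaks the ratios were 1.95 and 1.75.

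**Figure D1:**
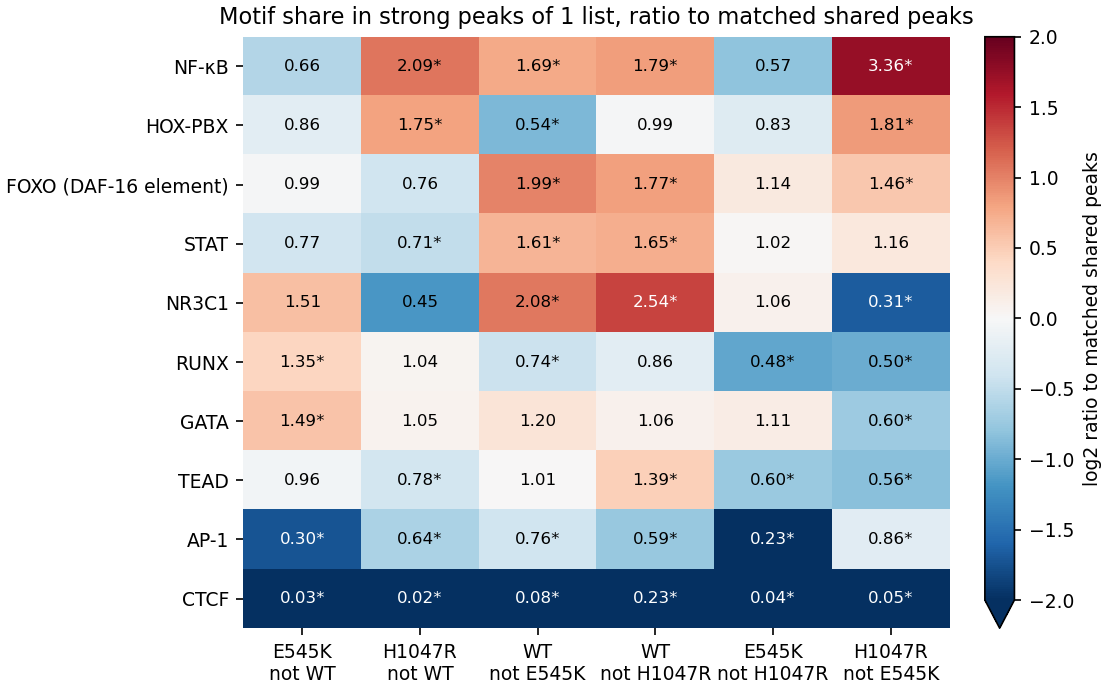
Share of strong unpartnered peaks with a motif within 100 bp of the summit, divided by the mean share of 1000 draws of shared peaks of the same list matched on GC content and area, for 10 of the 25 motifs (vertical) and the 6 ordered pairs of lists (horizontal); colour gives the log2 ratio (the lowest values share 1 colour) and an asterisk marks a share outside the central 95% of the draws. NF-κB is highest in H1047R peaks absent from E545K (3.36). FOXO, STAT, NF-κB and NR3C1 (glucocorticoid receptor) elements are above 1.5 in both sets of WT peaks.

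The comparison of E545K with H1047R asked where the mutants differed from each other. E545K held 11 strong peaks without an H1047R partner nearest the start of ADGRB1 and 8 nearest ARC, the latter not within the gene. It held 6 each nearest PTPN14, a phosphatase gene of YAP regulation (chromosome 1, 214348700 to 214552449), CAV1, the gene of caveolin (chromosome 7, 116524994 to 116561179), and NEDD9. Peaks covered 82.4% of the CAV1 gene body in E545K, 63.1% in WT and 13.4% in H1047R. H1047R in turn held 6 nearest the start of TTC39C, 5 nearest PLA2R1 (chromosome 2, 159932006 to 160062615) and 4 nearest TRAF3IP3. It also held 4 each nearest APOL1 (chromosome 22, 36253071 to 36267530) and VAV3 (chromosome 1, 107571161 to 107965180). On chromosome 2, 10 consecutive H1047R regions without an E545K partner (160110427 to 160139063) lay inside ITGB6 and outside PLA2R1. On chromosome 18, 12 such regions (23929072 to 23957272) lay outside TTC39C.

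Among the gene lists only housekeeping genes stood outside the central 95% of random lists (98.0 percentile), with 5 E545K peaks at YWHAZ and 1 H1047R peak each at GUSB and TFRC, and the sign turned when strength was set by summit value (net -0.0417) or all unpartnered peaks were used (-0.33). The inflammatory list had 3 such peaks in E545K and 7 in H1047R (14.4 percentile), with CCL20, a chemokine gene, at 2 in H1047R and NFKBIZ at 2 in E545K. The CCL20 promoter had a peak in WT (307) and H1047R (1423) and none in E545K, as did that of HOXB2 (1683 and 1233) and CA9, a hypoxia-induced gene (454 and 812). The YAP and TEAD list had 6 in E545K, all at PTPN14, and 5 in H1047R, 2 of them at ASAP1 and 2 at TEAD1 (82.2 percentile). The glycolysis and hypoxia list had 0 in E545K and 4 in H1047R, 2 of them at NDRG1 (10.1 percentile). At DUSP5, an ERK phosphatase gene, the net was 4 strong peaks toward E545K, and at ITGB4 also 4.

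Each list result in this paragraph, counted on strong peaks by area, lay inside the central 95% of random lists. With all unpartnered peaks some lay outside. In E545K against WT these were junction genes (99.8 percentile), transition and fibroblast genes (0.825) and neural and endothelial markers (0.525). In H1047R against WT they were keratinocyte genes (99.0) and FOXO targets (2.3). Toward E545K and toward WT, strong unpartnered peaks numbered 4 and 4 for basal and myoepithelial markers, with 2 of the WT peaks at ANXA8, and 2 and 0 for luminal markers, both at EHF. They numbered 3 and 0 for junction genes, 1 and 1 for transition and fibroblast genes, 0 and 1 for glycolysis, 3 and 3 for sterol and fatty acid synthesis, 2 and 1 for amino acid response genes, 3 and 3 for inflammatory genes, 0 and 0 for interferon response genes, 4 and 2 for YAP and TEAD targets, with PTPN14 at 3 in E545K, and 2 and 1 for p53 targets. Toward H1047R and toward WT, basal markers had 6 and 5, with CDH3 at 2 in H1047R and ANXA8 and ITGB4 at 2 in WT, and luminal markers 2 and 0, at EHF and ELF3. FOXO targets had 3 and 4, with TNFSF10 at 2 in H1047R and FBXO32 at 2 in WT, ERBB genes 4 and 2, TGF-beta and WNT genes 7 and 4, with SMAD3 at 2 in H1047R, and sterol genes 5 and 3, with INSIG1 at 2 in H1047R. Amino acid response genes had 2 and 3, with SLC7A11 at 2 in WT, glycolysis genes 1 and 0, interferon genes 2 and 0, YAP and TEAD targets 1 and 0 and keratinocyte genes 2 and 0, at KLK7 and KLK10. HOX genes had 1 and 1 in both of these comparisons. Among markers of other cell types the immune list had 3 and 2 toward E545K and WT and 2 and 0 toward H1047R and WT, and the neural and endothelial list 1 and 2 and 0 and 2. Between E545K and H1047R, FBXO32 gave 3 of the 5 FOXO target peaks of E545K, EPGN both ERBB peaks, TGFBR2 2 of 3 TGF-beta and WNT peaks and SLC7A5 both amino acid response peaks.

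E545K had 8170 peaks without an H1047R partner (9.14%, 8.95 to 9.33) and H1047R 25237 without an E545K partner (23.6%, 23.4 to 23.9). The strong counts were 717 (1.60%, 1.49 to 1.72) and 1531 (2.87%, 2.73 to 3.01). With lists of equal length this asymmetry was not kept, with 13076 and 13196 peaks, and 1009 and 680 strong peaks, without a partner. The 717 strong E545K peaks were wide and low, with a median width of 1524 bp and a median summit -log10 p of 2.96, against 564 bp and 4.23 for the 1531 of H1047R. The strongest E545K examples included peaks in TSNARE1 (chromosome 8, 142271581 to 142282616, area 6614) and near CAVIN2, a caveola gene (chromosome 2, 191829959 to 191833907, area 6472). Those of H1047R were the TRAF3IP3 and CTNNB1 peaks and a peak toward TTC39C (chromosome 18, 23931561 to 23939640, area 10410). Promoter peaks were one-sided at 258 genes toward E545K, with the largest at ENSG00000257341 (13840), MAMDC4 (9668), ADAM8 (8705), LIME1 (8209) and ENSG00000273088 (7161), all of which reached an H1047R peak outside the window. Toward H1047R there were 344, and beside SLC17A7 (5375) and ENSG00000285920 (3352) they included TRAF3IP3, IL1RL2, an interleukin receptor gene (2348), and BRSK2 (2255), whose peaks had no E545K partner.

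The NF-κB motif lay near the summit of 7.12% (interval 5.94 to 8.52) of the strong H1047R peaks absent from E545K against 2.12% of matched peaks, a ratio of 3.36. In the strong E545K peaks absent from H1047R the share was 1.26% (0.66 to 2.37) against 2.18%, inside the central 95% of the draws. Over whole peaks both sets held more of it than matched peaks, 12.8% against 4.99% in H1047R and 13.9% against 7.97% in E545K, ratios of 2.56 and 1.75. Width was not matched, and these E545K peaks had a median of 1524 bp against 888 bp for strong E545K peaks with a partner. HOX-PBX stood at 1.81 times the matched share in H1047R and GATA at 0.60 times. The FOXO element, in excess in WT peaks above, also stood at 1.46 times in these H1047R peaks, outside the draws. RUNX and TEAD were low on both sides, at 0.50 and 0.56 times in H1047R and 0.485 and 0.599 times in E545K. Over whole peaks RUNX, TEAD and GATA in H1047R returned inside the draws (0.891, 0.94 and 0.975), while RUNX and TEAD in E545K rose to 1.36 and 1.38. With strength and matching by summit value, RUNX and TEAD in E545K stood at 0.972 and 1.34, inside the draws. In H1047R they stayed low, at 0.465 and 0.476. CTCF motifs were nearly absent from strong unpartnered peaks of each ordered pair, between 0.02 and 0.23 times the matched share. Among all unpartnered peaks the ratio was 0.957 for WT against E545K, 0.79 for WT against H1047R and 0.47 for H1047R against E545K, and from 0.124 to 0.231 in the other pairs. AP-1, at 0.23 times in these E545K peaks and 0.86 times in these H1047R peaks, rose to 1.4 in H1047R with all unpartnered peaks. By summit value only 237 E545K peaks were strong and unpartnered and the net was 0 at ADGRB1, ARC, PTPN14 and NEDD9 and -1 at CAV1. The net at TTC39C, PLA2R1 and APOL1 also fell to 0 by summit value, while VAV3 had 5.

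Regions with a peak in both mutants and none in WT numbered 5568 of 120615 merged regions, against 11766 in WT and H1047R alone and 2571 in WT and E545K alone. A region without a called peak is not shown to be closed. Of the peaks without a WT partner, 10.1% in E545K and 8.22% in H1047R were strong. The regions of WT missing from both mutants numbered 8118. The AJAP1, TSHZ3, CSF3, EREG, PCK1 and WT1 loci held regions or promoters of the latter kind, and the KLK7, KLK10, NGFR and WNT10A promoters of the former. Because both mutants share the WT list, 20 simulations were run in which no region differed and only list length and detection noise did. The noise was a single standard deviation of 0.394 log2 units, which no replicate values could check. Any excess over the simulations therefore depends on that setting and does not show that regions differ beyond true detection noise. They gave 2484 regions (2340 to 2569) present in both mutants alone and 2667 (2596 to 2738) present in WT alone. Each other class of regions in only some lists also exceeded its simulation, with 5450 against 652 in E545K alone, 2571 against 693 in WT and E545K, 13310 against 9065 in H1047R alone and 11766 against 9335 in WT and H1047R, so the excess was not particular to regions shared by the mutants. Independent draws from all 120615 regions would share 1724 of the regions without a WT peak and 1762 of those with a missing WT peak. That base includes regions that neither set could hold by definition, so these values do not measure sharing between the mutants. The WT samples were pooled and could not be split between the comparisons, so the part of the excess owed to the shared WT list was not separated.

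**Figure D2:**
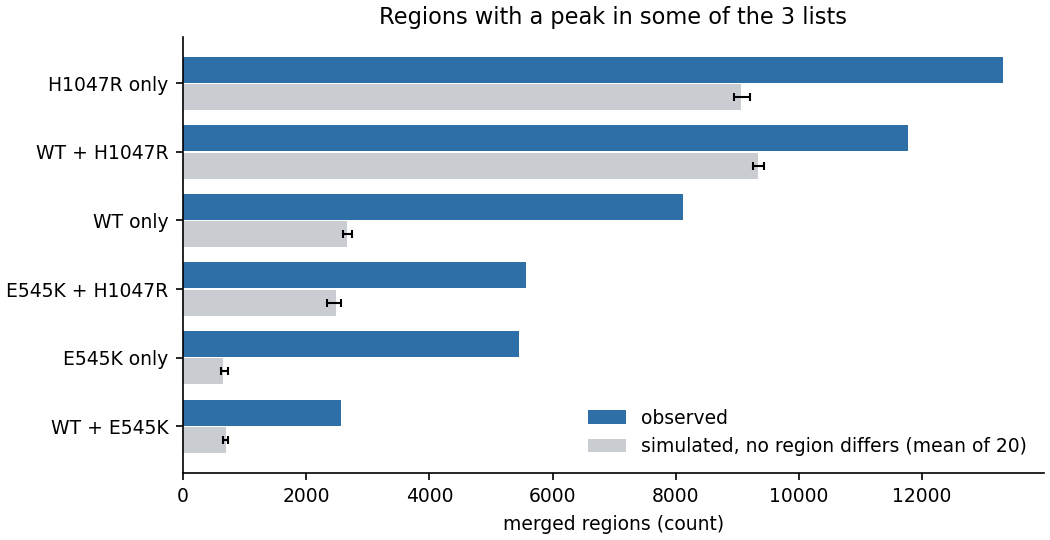
Merged regions (count, horizontal) with a peak in only some of the 3 lists, observed and as the mean of 20 simulations in which no region differs, with bars from the lowest to the highest simulation. All 6 classes exceed their simulation, among them E545K alone (5450 against 652), both mutants alone (5568 against 2484) and WT alone (8118 against 2667). The simulated noise, 0.394 log2 units, had no replicate check.

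Rank shifts and strong unpartnered peaks were also summarised along the genome. Among windows of 5 Mb with at least 20 shared regions, 8 had shared peaks ranking at least 5 percentile points lower in both mutants than in WT, and all 8 lay among the 9 windows of the short arm of chromosome 5. On that arm the median rank of 818 shared regions was lower by 7.69 points in E545K (change -7.69, bootstrap interval -8.67 to -6.69) and 7.35 points in H1047R (-7.35, -8.17 to -6.16), with shifts of 0.81 and 0.37 on the long arm. The ranks were taken within the same 69662 shared regions in each list. WT had 1489 peaks on the short arm (1.51% of its list), E545K 1055 (1.18%) and H1047R 1225 (1.15%). At the end of chromosome 8, the window from 140000001 to 145000000 held 68 strong E545K peaks without a WT partner, where no other window exceeded 13. Over about the last 4 Mb of the arm, peaks covered 1317 kb in E545K, 624 kb in WT and 537 kb in H1047R. The 67 unpartnered strong E545K peaks there had a median width of 2412 bp and a median summit -log10 p of 2.45. ADGRB1, with peaks over 83.7% of its gene body in E545K, 15% in WT and 8.73% in H1047R, ARC and ZC3H3 lie in this segment. A single window was higher by at least 5 points in both mutants (chromosome 4, 170000001 to 175000000, by 6.58 and 7.93).

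**Figure D3:**
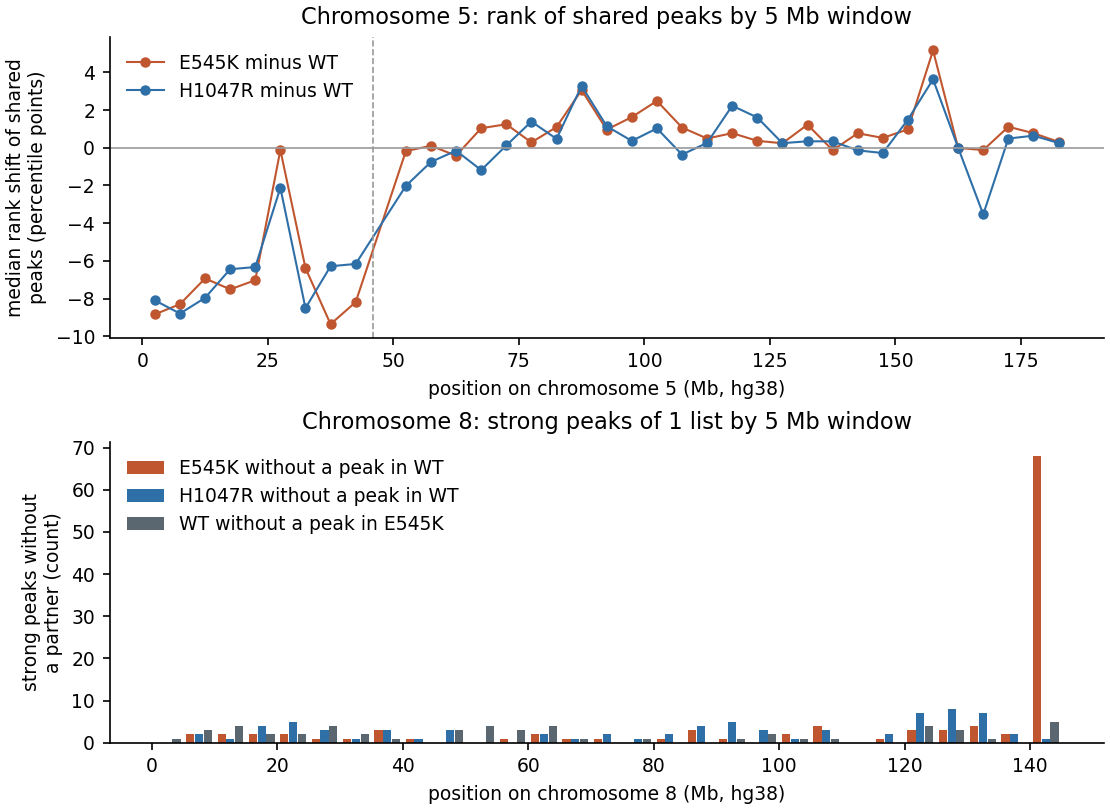
Top, median rank shift of shared peaks (percentile points) in E545K and H1047R against WT for each 5 Mb window of chromosome 5 (Mb, hg38), with a dashed line at 46 Mb marking the end of the short arm. Bottom, count of strong peaks without a partner per 5 Mb window of chromosome 8, where the last window holds 68 E545K peaks.

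**Figure D4:**
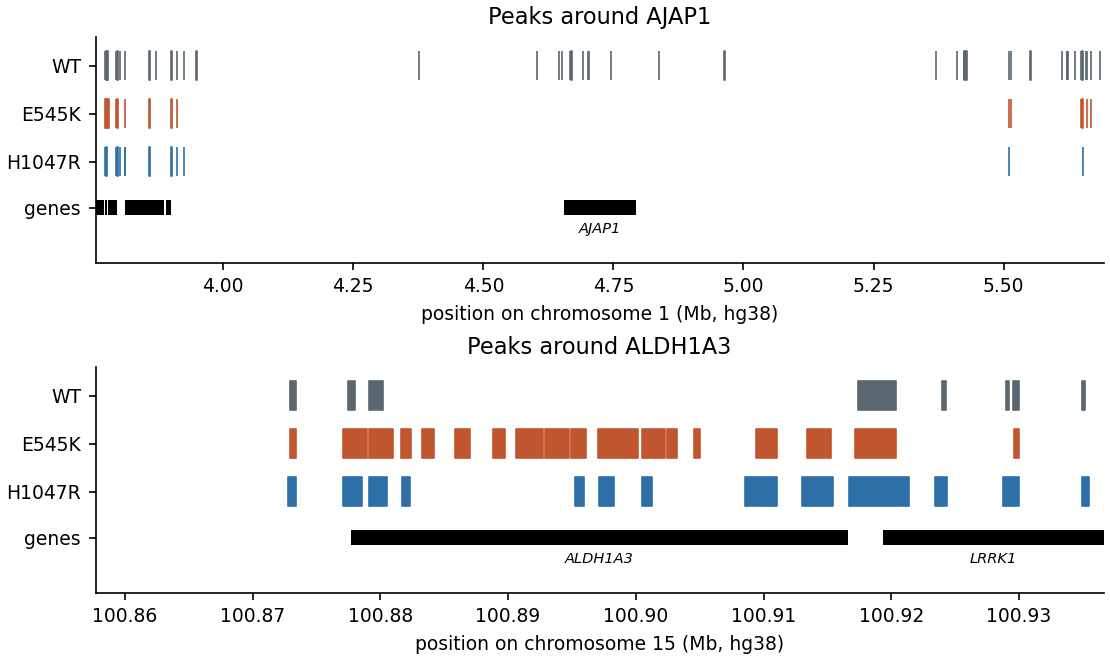
Peaks of each list (coloured boxes, to scale) and protein-coding genes (black boxes, the longer ones named) around AJAP1 on chromosome 1 and ALDH1A3 on chromosome 15, against position in Mb (hg38). AJAP1 carries 6 gene-body peaks in WT and none in either mutant, and the ALDH1A3 gene body carries 16 peaks in E545K, 9 in H1047R and 2 in WT.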

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

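The tests with strength by summit value for gene lists, motifs and loci, the other settings for loci, and those without the short arm of chromosome 5 and the end of chromosome 8 were chosen only after the results were seen. No paired analysis was possible because each genotype has 1 pooled peak list and no values per sample, and no replicate could be left out for the same reason. Among results that answer a comparison, 68 values under an alternative stayed within 1.5 times the reported count and 16 moved further. For gene lists and motifs what counted was whether a value stayed on its side and outside the central 95%, whatever its size, and for loci whether the net stayed within 1.5 times. By these measures 155 values were kept, 78 were not and 31 changed sign or side of 1. The cause was not tested unless named. Unknown depth limits all counts of peaks without a partner. Neither depth nor library quality was tested as a source of the wider, lower E545K peaks (median 539 bp and summit -log10 p 3.97, against 466 bp and 4.25 in WT), on which the loci led by ADGRB1 and ALDH1A3 rest.

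When a partner had to cover 50% of the peak's own length, a stricter demand that leaves more peaks unpartnered, strong unpartnered peaks numbered 2638 for E545K and 2143 for WT in their comparison, 3384 for H1047R and 1679 for WT in theirs, and 1912 for E545K and 3100 for H1047R. With strength by summit value, strong E545K peaks absent from WT numbered 658 and those absent from H1047R 237. With lists of equal length, strong WT peaks absent from E545K numbered 687, strong H1047R peaks absent from WT about 1.0e+03 (2.34% of the strong peaks) and from E545K 680, and all unpartnered peaks of E545K and H1047R against each other 13076 and 13196. Gene lists outside the central 95% of random lists numbered 3 with strength by summit value, of which 1 was among the reported 7. Motif and set pairs outside the draws numbered 83 with whole peaks and 91 with all unpartnered peaks, against the reported 51, of which 30 and 36 were kept. The draws for whole peaks were not matched on width.

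With all unpartnered peaks the net of the transition and fibroblast list turned to 0.12 in H1047R against WT, and that of the housekeeping list to -0.33 in E545K against H1047R. By summit value the housekeeping list turned to -0.0417 in that comparison and to 0.0417 in H1047R against WT, and CAV1 to -1. Motif ratios crossed 1 with all unpartnered peaks as follows. H1047R peaks absent from E545K gave AP-1 1.4, FOXO 0.995, KLF-SP 1.03 and NRF2 1.05, and those absent from WT AP-1 1.21 and NRF2 1.01. E545K peaks absent from H1047R gave ETS 1.12, RUNX 1.21 and TEAD 1.43. WT peaks gave NF-κB 0.567 against H1047R and the glucocorticoid receptor element 0.942 against E545K. With strength by summit value, AP-1 was 1.17 in H1047R peaks absent from E545K, KLF-SP 1.81 and TEAD 1.34 in E545K peaks absent from H1047R, and KLF-SP 1.01 in E545K peaks absent from WT. With whole peaks, E545K peaks absent from H1047R gave KLF-SP 1.32, NRF2 1.55, RUNX 1.36 and TEAD 1.38, and those absent from WT KLF-SP 1.29 and NRF2 1.22. H1047R peaks gave NRF2 1.07 against E545K, and NRF2 1.06, STAT 1.09 and TEAD 1.13 against WT, and WT peaks gave NRF2 1.12 against H1047R.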

Other observations

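Tests of a gain at the end of chromosome 8, of GC-rich windows, of chance runs and of lost DNA were chosen only after the results were seen. WT peaks without a partner formed runs of at least 10 consecutive regions, 21 against E545K and 24 against H1047R, of which 12 overlapped. A run of 22 regions, the greatest length found, on chromosome 19 from 30082014 to 32104830 around ZNF536 and TSHZ3, was absent from both mutants. Another run, on chromosome 16 from 35134510, held 22 regions against E545K (to 36072534) and 21 against H1047R (to 35733680). It held no start of a protein-coding gene, and its median areas were 725.5 and 683.2. Others absent from both lay around AJAP1 on chromosome 1 (19 and 18 regions), CNTNAP5 and GYPC on chromosome 2 (14 regions, 123495306 to 126658466) and SOX1, a neural transcription factor gene, on chromosome 13 (12 regions, 111903084 to 112398496). TSHZ3 carried 4 gene-body peaks in WT and AJAP1 6, and neither carried any in the mutants. Runs without a WT partner numbered 5 in E545K and 2 in H1047R. The longest in either list lay on chromosome 1 from 49102718 to 49728880 (13 and 15 regions), in both mutants. H1047R held a run of 14 regions without a WT partner inside KLF7, a zinc-finger gene (chromosome 2, 207081867 to 207116226), whose gene body carried 18 peaks in H1047R and 10 in WT but was covered to 18.0% and 19.4%.

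Promoter peaks without any partner, chosen after their values were seen, included S100A7, which encodes the keratinocyte protein psoriasin (area 1384), and RSPO2, a WNT agonist gene (1265), in H1047R alone. LYPD2 (1583) had one in E545K alone and DCP1B (1155) in WT alone. PRDM9 had one in E545K (2925) and WT (2154) and none in H1047R, and ARHGAP28 in H1047R (2142) and E545K (1596) and none in WT. CDKN2A and CDKN2B, cell cycle inhibitor genes, had 0 peaks in any list. They lay in a gap of 356.6 kb in WT and E545K and 303.8 kb in H1047R. The neighbouring MTAP (chromosome 9, 21802636 to 21937651) had 6 peaks in each list. The gap began inside MTAP, at 21855139 in WT, so the rest of that gene also lay in the gap.

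Shared peaks on the short arm of chromosome 5 ranked lower in both mutants, by -7.69 and -7.35 points. GC content was argued against by GC-matched regions elsewhere, which shifted by at most -0.358, and a general loss of rank of weaker peaks by area-matched regions, at -0.554. Fewer copies of the arm in the knock-in lines, or more in the WT population, may account for the shift. Of the promoter regions on the arm 91.5% in E545K and 88.7% in H1047R ranked lower, and other regions moved by -8.71 and -8.16, but promoter regions moved by -2.77 and -2.53, between the bounds set for and against, so this stays open. Genotype, clonal origin and maintenance EGF differ together and were not tested.

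Strong E545K peaks without a WT partner crowded the end of chromosome 8. GC-rich windows in general were argued against, since no other window with peaks as GC-rich held more than 10. A gain of the segment in the E545K line could widen its peaks, but shared regions there ranked higher by 1.93 points, between the median (-0.208) and the upper end of the central 95% (2.13) of blocks elsewhere, so it stays open. No biological explanation was tested.

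The runs of missing WT peaks exceeded those from independent placement of the missing peaks. In 100 shuffles within area deciles at most 0 such runs arose, where 21 were observed against E545K. The shuffles keep no correlation between neighbouring peaks, so they cannot exclude chance in a signal that varies by region. Peaks near the calling threshold stay open, as the median area in the runs was at least 1.35 times that of all unpartnered WT peaks, short of the bound set against it. Loss of the segments from the DNA cannot be told apart from closed chromatin for the 12 runs missing from both mutants, because a run holds no mutant peak by its definition. The segments may thus be closed, lost or below the calling threshold, and genotype and maintenance EGF were not tested.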
